A study of Homo sapiens with 15 samples.

How the data were processed

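Total RNA of 15 cultures of a HEK293 line (human embryonic kidney cells, here the Flp-In T-REx derivative that takes up an inducible transgene) was labelled with biotin and hybridized to Illumina bead arrays, per the labels. The 5 groups held 3 biological replicates each, per the series' design text. The vector group was the parental line. 2 stable lines carried 3xFLAG-tagged ZMYND8, as wild type or with a bromodomain mutation, and were induced for 24 h. The inducer is given as 100 nM doxycycline in the design text and as 1 µg/ml tetracycline in the treatment protocol, and no label says whether vector cells received either. The mutation is written N228F in the descriptions and N288F in the sample titles, and N228F is used throughout. The remaining groups were cells reverse transfected for 48 h with 100 pmol of a control siRNA or of an siRNA against ZMYND8.

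The raw intensity of each probe was the bead-averaged signal exported from GenomeStudio without background subtraction or normalization, per the file headers (export version 1.9.0). The detection p-value of each probe on each array, computed by the same software against that array's negative controls, was deposited beside it. The deposited log2 table of 22839 probes and the log2 values attached to each sample were made by the authors with GenomeStudio, R 3.2, lumi 2.20.2 and limma 3.24.13, per the submitters' processing notes, which give no settings. In the deposited log2 values the 9 overexpression arrays shared a median of 7.88 and the 6 siRNA arrays a median of 8.37, so the arms look normalized apart from each other. The authors' p-value in that table belongs to an F test over their 3 comparisons together, per the file headers. Its 15 sample columns carry numbers that no label maps to a group and were left out.

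The raw intensities were used. They were background-corrected and normalized with neqc of limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8): normexp with negative-control parameters taken from the detection p-values, an offset of 16, log2 and quantile normalization over all 15 arrays. Quantile normalization assumes that the arrays share 1 distribution of signals, so a change in total RNA output could not be seen. The file listed 47323 probes, of which 93 were control probes and 3270 had no gene symbol. Current symbols were found for 35672 probes, and 8288 kept the symbol of the file. Probes were kept where the detection p-value was under 0.01 on at least 3 arrays, which left 19373. The probe with the highest mean over all arrays stood for its gene, which gave 14883 genes, 701 of them probes without a symbol. 3583 genes had several kept probes. Probes of the same gene were called in opposite directions for 58 genes in wild type against vector, 41 in N228F against vector, 13 in N228F against wild type, 1 in ZMYND8 siRNA against control siRNA and 202 in control siRNA against vector.

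A linear model with 1 mean per group was fitted to all 15 arrays with lmFit and eBayes (10 residual and 2.99 prior degrees of freedom). Each comparison was tested two-sided with limma's moderated test, adjusted by Benjamini and Hochberg over the 14883 genes, and a gene was called where the adjusted p was under 0.05. Replicate numbers were not used as a block. The 3 ZMYND8 probes were tested in a like fit over the 19373 kept probes, adjusted over these. The SE of a log2 difference comes from these fits, and ± gives the SD of 3 arrays. Where no array of a group detected a gene, its fold is given only as at least N-fold, computed against the lowest signal detected on each of those arrays. Such a bound holds only on the background-corrected scale used here. 24 gene lists with 629 genes, of which 507 were measured, were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists within a comparison. Camera with an estimated correlation and fry were alternatives. Where a member of a list was not detected, the list's median is also given with that member at its bound, or at 0 where no bound could be set.

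The named genes of a comparison were ZMYND8, the 12 genes with the largest positive and the 12 with the largest negative difference among called genes with a known symbol whose arrays did not overlap between the groups, up to 4 members of each list with the smallest p, and the 8 genes with the largest opposite changes in knockdown and overexpression. Some genes within this rule are not reported here. This rule, the lists, the tests and the alternatives not named below as added were fixed before the data were examined. Genes were ranked on fitted differences, also where only a bound is printed. The alternatives were the authors' log2 values per sample, no background correction, median scaling, no or another detection filter, all probes, only the compared groups in the fit, a replicate block, a trended and robust variance, array weights, a 1.5-fold minimum, an adjusted p of 0.01 and leaving out each array. A fit of each arm on its own was added after seeing the data, as were several of these alternatives for the gene lists, for the knockdown genes in overexpression and for the comparison of the lines.

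The code was tested on simulated data drawn around the groups' real means and spread, with 200 of 14883 genes changed, 50 at each fold size. In the wild-type comparison 20% of the genes changed 1.25-fold, 54% at 1.5-fold, 86% at 2-fold and 100% at 4-fold were called, with 8 false calls. In N228F against vector the shares were 18%, 74%, 94% and 100%, with 14 false calls. For N228F against wild type they were 24%, 62%, 96% and 100% with 7 false calls. For ZMYND8 siRNA against control siRNA they were 22%, 70%, 100% and 100% with 11, and for control siRNA against vector 20%, 62%, 96% and 100% with 7. A list shifted by 0.3 in simulated ZMYND8 siRNA data was called in 20 of 20 runs, and 0 of 460 tests of other lists were called at an adjusted p under 0.05. The simulated genes varied independently of each other, so these runs do not test the preset correlation where members of a list vary together. The number of arrays limits the precision. The 92 ERCC probes were detected on 0 of the 15 arrays and could not be used for scaling.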

Results

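Gene expression was measured on 15 Illumina arrays of HEK293 cells in which ZMYND8, a chromatin reader with a PHD finger, a bromodomain and a PWWP domain, was induced or depleted. Each of the 5 groups held 3 biological replicates: vector cells, cells with induced wild-type ZMYND8, cells with induced ZMYND8 N228F, cells with a control siRNA and cells with an siRNA against ZMYND8. The mutation lies in the bromodomain, the part that binds acetylated lysine. The 9 arrays of the overexpression arm had mean raw signals of 365 to 419 and detected 15642 to 17167 probes. The 6 siRNA arrays had mean signals of 531 to 644 and detected 17722 to 18272 probes. Normalized log2 signals of replicates correlated across genes with r between 0.991 and 0.997, where genes are not independent replicates. The p-values below measure the spread between these samples, each from limma over 14883 genes unless said otherwise, and a called gene had an adjusted p under 0.05.

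The ZMYND8 transcript was read by 3 probes on chromosome 20, minus strand, with positions as the file gives them and no genome build named. The p-values of these probes, here and below, come from a limma fit over the 19373 kept probes. The probe from transcript base 3413 (45841314 to 45841363) was not detected on any array of vector cells or of either siRNA group. It read 7.90 ± 0.25 in wild-type cells, at least 5.07-fold above vector (adjusted p = 7.36e-11), and 8.67 ± 0.09 in N228F cells, at least 8.67-fold above vector (adjusted p = 1.01e-11). The probes from bases 4068 (45838756 to 45838805) and 4164 (45838819 to 45838868) were detected in every group. They read 7.56 ± 0.08 and 7.58 ± 0.08 in vector cells and differed from this in wild-type cells by -0.04 (SE 0.10) and -0.18 (SE 0.13), with no call (adjusted p = 0.756 and 0.264). In N228F cells they rose to 8.22 ± 0.16 and 8.32 ± 0.04 (adjusted p = 0.00017 and 0.000367). With ZMYND8 siRNA the probe from base 4068 fell from 7.37 ± 0.12 to 6.36 ± 0.13, and that from base 4164 from 7.41 ± 0.14 to 6.26 ± 0.11, which left 45.1% of the control siRNA level (adjusted p = 3.06e-05 and 5.64e-05). The files do not say which of the probes lie within the construct.

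**Figure D1:**
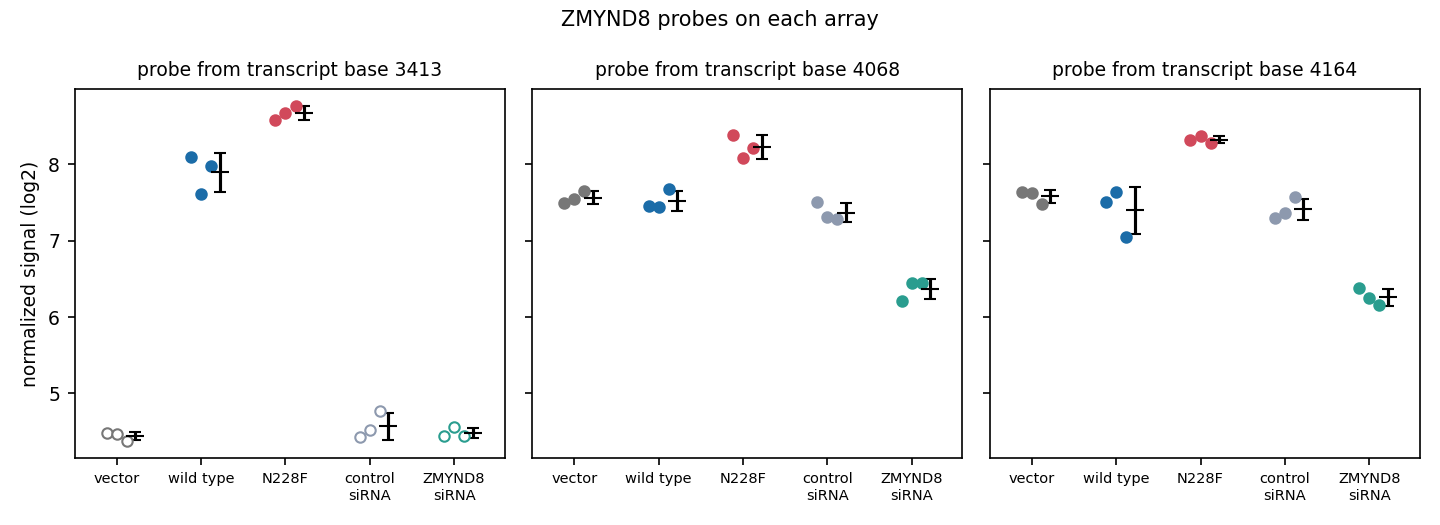
Normalized log2 signal of the 3 ZMYND8 probes on each array, by group; filled points were detected, open points were not, and the bar is the mean ± SD of 3 arrays. The probe from base 3413 was detected only in the induced lines, and the others were lowest with ZMYND8 siRNA.

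Cells with induced wild-type ZMYND8 were compared with vector cells to ask which genes differ when more ZMYND8 is made. Epithelial genes were far higher: EPCAM, a cell adhesion molecule of epithelia, was 43.7-fold higher (log2 difference 5.45, SE 0.15, adjusted p = 5.28e-12) and the keratin gene KRT8 was higher by 3.59 (SE 0.08). KRT19, another keratin, was at least 30.3-fold higher, and CDH3 (P-cadherin) at least 3.33-fold. Other large rises were SLFN11, which blocks replication forks under stress, at least 50.1-fold, OCIAD2 at least 43.7-fold, DPYSL3 at least 31.1-fold and CYP4X1 at least 21.8-fold. The size of these folds depends on the background correction: the authors' log2 fold changes for wild type were only 2.80 for SLFN11 and 2.60 for OCIAD2. The retrotransposon-derived gene PEG10 was at least 17.4-fold higher, ZNF544 at least 16.4-fold, CEBPE at least 16.3-fold, MGMT, which repairs alkylated DNA, at least 13.1-fold, and RIOX1 at least 12.5-fold. LCP1, an actin-bundling protein of white blood cells, was higher by a log2 difference of 5.55 and was detected on 1 of 3 vector arrays. The glutathione transferase genes GSTM1 and GSTM2, close relatives of similar sequence, were each at least 42.6-fold lower. PLIN2, which coats lipid droplets, was at least 21.3-fold lower. SNAI2, a repressor of epithelial genes, and the globin gene HBQ1 were each at least 20.9-fold lower. The neuropeptide gene GAL was lower by at least 20.7-fold, ISL1 at least 14.1-fold, ZNF22 at least 13.9-fold and PNMA8A at least 12.8-fold. AMOT, which binds YAP, was 22.8-fold lower (log2 difference -4.51, SE 0.09, adjusted p = 2.07e-13). NEFM, a neurofilament gene, and PRTFDC1 differed by -5.38 and -4.58, each detected on 1 of 3 wild-type arrays.

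In all, 7529 of 14883 genes were called in wild type against vector, 3550 higher and 3979 lower. At least 2-fold differences numbered 668 higher and 471 lower. Of the 10 measured epithelial genes 7 were higher, 1 was lower and 2 were not called, and 7 and 1 when adjusted over the list alone (median 2.73, or 1.71 with undetected members at their bound, adjusted camera p = 1.40e-05, and adjusted p = 0.0241 with an estimated correlation). This call was lost when only genes detected on all 15 arrays were kept (adjusted p = 0.0583). Of 18 heat shock genes 12 were lower and 1 was higher, also adjusted over the list alone, among them DNAJB1 (-0.72) and HSPH1 (-0.68), which help proteins fold (median -0.25, adjusted camera p = 0.0322, but adjusted p = 0.277 with an estimated correlation). Of 21 immediate early genes 12 were higher and 1, KLF2 (-0.70), was lower, the same numbers as when adjusted over the list alone. The phosphatase gene DUSP5 was 2.79-fold higher, DUSP6 at least 1.85-fold, and ZFP36 was higher by 0.98 (list median 0.36, or 0.27 with bounds, adjusted camera p = 0.0235, but adjusted p = 0.310 with an estimated correlation). Without vector replicate 3 the adjusted p of both of these lists was 0.0556, and without wild-type replicate 1 that of heat shock genes was 0.0622. Both of these calls were also lost among genes detected on all 15 arrays (adjusted p = 0.0583 for each).

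Cells with induced N228F were compared with the same vector cells to ask what the bromodomain mutant changes. The genes with the largest rises included SLFN11 (at least 51.5-fold), OCIAD2 (at least 36.2-fold), KRT19 (at least 29.1-fold) and DPYSL3 (at least 29.2-fold). Next came ZNF544 (at least 17.2-fold), CYP4X1 (at least 16.3-fold), PEG10 (at least 16.2-fold), CEBPE (at least 15.2-fold), and MGMT and RIOX1 (each at least 13.1-fold). EPCAM rose 39.7-fold (log2 difference 5.31, SE 0.15, adjusted p = 8.49e-12), and LCP1 by 5.21, detected on 1 of 3 vector arrays. GSTM1 and GSTM2 were at least 43.3-fold lower, NEFM at least 39.4-fold, SNAI2 at least 21.2-fold, GAL at least 21.1-fold and PABPC4L at least 11.3-fold, and PNMA8A was again among the largest falls. PLIN2 (-4.64) and NMRAL1 (-4.26) were detected on 1 of 3 N228F arrays, and LRATD2 (-4.31) and PRTFDC1 (-4.21) on 2 of 3. In all 7267 genes were called, 3502 higher and 3765 lower, with 628 higher and 401 lower by at least 2-fold. Epithelial genes were higher for 7 of 10 members and lower for 1, also adjusted over the list alone, with KRT8 higher by 2.67 and the tight junction gene CLDN1 at least 5.40-fold (median 0.54, or 0.42 with bounds, mean 1.81, adjusted camera p = 0.0025, but adjusted p = 0.125 with an estimated correlation). Among genes detected on all 15 arrays that adjusted p was 0.115. Heat shock genes were lower for 12 of 18 members and higher for 1, also adjusted over the list alone, with HSPB1 at -1.22 and HSPH1 at -0.75 (median -0.27, adjusted camera p = 0.00893, but adjusted p = 0.166 with an estimated correlation).

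The differences of both lines from vector lay close together. Across genes, which are not independent replicates, their log2 differences correlated with r = 0.884, against 0.500 in simulated unchanged groups that shared the same vector arrays. Their covariance was 0.354, against 0.00989 in those simulations. Calls shared by both lines numbered 2676 higher and 2837 lower, and 121 genes were called in opposite directions. Independent calls would share 835 and 1007, but these calls are not independent, as both use the same vector arrays. In the 100 simulations no gene was changed, so their mean of 0 shared calls gives no chance level for lines with many calls. The slope of the N228F difference on the wild-type difference was 0.857 over genes called in wild type and 0.923 over genes called in N228F. The 3 vector arrays stood in both differences and were too few to be divided between them.

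**Figure D2:**
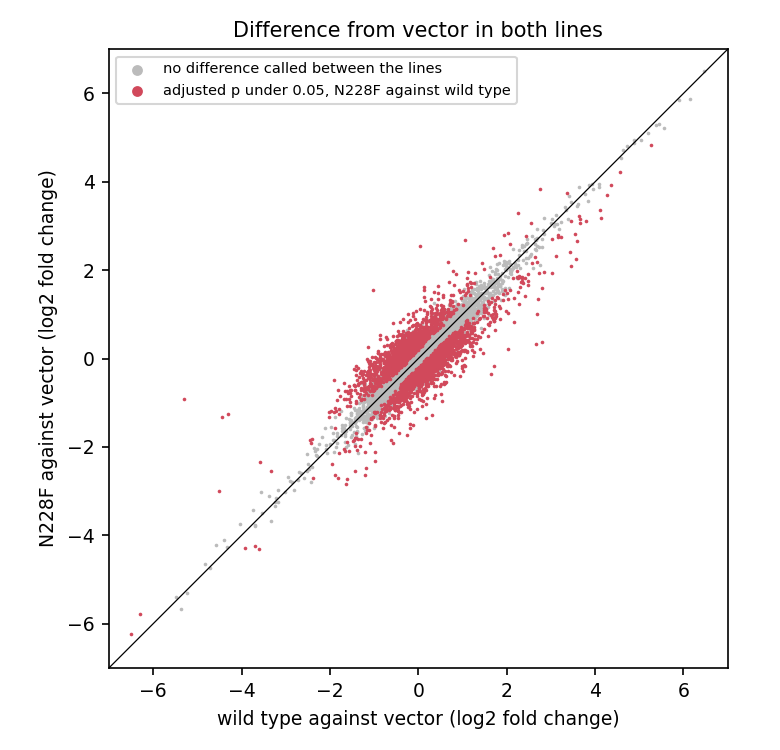
Log2 difference from vector of 14883 genes in wild-type cells (x axis) and N228F cells (y axis), with the line of equal change; red points were called between the lines. Most genes lie along the line (r = 0.884), and points of genes not detected in a group show fitted values, not bounds.

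N228F cells were compared directly with wild-type cells, a comparison free of the vector arrays. Genes of the ATF4 response, which makes and imports amino acids under stress, were lower in N228F cells: SLC7A5, a leucine transporter, was 2.16-fold lower (log2 difference -1.11, SE 0.07, adjusted p = 5.61e-07). STC2 (-0.88), CTH (-0.83) and ASNS, which makes asparagine (-0.82), were lower as well. HBQ1 was at least 11.1-fold higher, ZNF22 at least 5.59-fold, the urea cycle gene CPS1 at least 4.64-fold, TSPY26P at least 3.29-fold, TIGD7 at least 2.37-fold, and SNX5P2 at least 2.24-fold. AMOT was 2.85-fold higher (1.51, SE 0.09, adjusted p = 2.20e-07), and TMEFF2 (1.51), LPAR2 (1.40) and the antisense transcripts HOXB-AS3 (1.41) and HOXA-AS3 (at least 1.65-fold) rose as well, with MEIS3P1 (1.62) detected on 2 of 3 wild-type arrays. CDH3 was at least 3.44-fold lower, the keratin gene KRT17 at least 3.33-fold, C2CD2 at least 3.25-fold, TCEAL7 at least 3.09-fold and LCN15 at least 1.97-fold. CRABP2, which carries retinoic acid, was 3.48-fold lower (-1.80, SE 0.13, adjusted p = 1.90e-06), followed by ALG1L1P (-1.58), RIPPLY3 (-1.53), SPACA9 (-1.47) and PDLIM7 (-1.38), and ECHDC2 (-1.66) and PIBF1 (-1.43) were each detected on 1 of 3 N228F arrays. The ZMYND8 probes were higher in N228F cells by 0.78, 0.71 and 0.92, in the order of their bases (adjusted p = 0.000641, 0.000486 and 0.000317 over the kept probes). ZMYND8 lies on chromosome arm 20q, where the median gene was higher by 0.29.

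In this comparison 2805 genes were called, 1413 higher and 1392 lower, of which 61 and 68 differed by at least 2-fold. Of 27 ATF4 genes 15 were lower, 1 was higher and 11 were not called, and 18 and 2 when adjusted over the list alone (median -0.35, or -0.31 with bounds, adjusted camera p = 1.00e-08, and adjusted p = 0.00381 with an estimated correlation). Of 10 epithelial genes 3 were lower and 7 were not called, with 4 lower when adjusted over the list alone (median -0.10, mean -0.62, adjusted camera p = 0.0171, but adjusted p = 0.145 with an estimated correlation). KRT8 was lower (-0.92), and CDH1 (E-cadherin), detected on 2 of 3 N228F arrays, differed by -0.53 without a call (adjusted p = 0.0602), which it gained without wild-type replicate 3 (adjusted p = 0.00315) or N228F replicate 2 (adjusted p = 0.0460). With no detection filter the adjusted p of the epithelial list was 0.0542, and among genes detected on all 15 arrays it was 0.488. With median scaling 1617 genes were called, 1124 higher and 493 lower, and with only these groups in the fit 1215 were called. The fit over all 15 arrays also takes its spread from the siRNA arrays, whose replicates lay closer together. Their pairs had median absolute log2 differences of 0.102 to 0.113, against 0.132 to 0.162 in the overexpression arm.

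The siRNA against ZMYND8 was compared with the control siRNA to ask which genes depend on ZMYND8. The largest falls included some neuroendocrine and synaptic genes: CHGA (chromogranin A, stored in secretory granules) was 10.2-fold lower (log2 difference -3.35, SE 0.19, adjusted p = 1.44e-07) and was detected on 1 of 3 ZMYND8 siRNA arrays. BSN (bassoon, a scaffold of the synapse) was 5.60-fold lower (-2.49, SE 0.10, adjusted p = 1.14e-08) and SYP (synaptophysin) 4.66-fold (-2.22, SE 0.08, adjusted p = 1.00e-08). CPLX1 was at least 3.91-fold lower, AP3B2 at least 3.51-fold, TCIM at least 3.37-fold, SCG3 at least 3.22-fold, ACTL6B, a neuronal subunit of a chromatin remodeller, at least 2.70-fold, CHGB at least 2.47-fold and INSM2 at least 1.98-fold. TMEM145 was 3.49-fold lower, and TMEM198 (-1.66) was detected on 2 of 3 ZMYND8 siRNA arrays. Genes that rose included ACLY, which makes cytosolic acetyl-CoA, at 2.44-fold (1.29, SE 0.09, adjusted p = 1.08e-06), and the cyclin genes CCNG2 (1.35, SE 0.10) and CCNE2 (1.34, SE 0.08). Others were TMT1A (1.49), CFAP144 (1.43), SPRING1 (1.33), the small nucleolar RNA SNORA12 (1.30), CLIC4 (1.29), the clock gene DBP (1.21), ZNF467 (1.21), EFR3A (1.20) and FST, at least 1.85-fold. In control siRNA cells all 12 of the genes named as lower were called higher than in vector cells, and ACLY was called lower than in vector cells. The same control siRNA arrays selected these genes, which favours such a pattern. With ZMYND8 siRNA the 12 genes differed from vector by -1.52 to 0.40 (median -0.30).

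Between the siRNA groups 2441 genes were called, 1244 higher and 1197 lower, with 33 higher and 85 lower by at least 2-fold. The number was 1624 without ZMYND8 siRNA replicate 3, 3994 with the authors' values and 3821 with array weights. Of 24 neuronal genes 17 were lower, 2 higher and 5 not called, also adjusted over the list alone, with CNTNAP2 at -1.13 (median -0.62, or -0.52 with bounds, adjusted camera p = 5.05e-11, and adjusted p = 0.000298 with an estimated correlation). Of 27 MYC targets and ribosome biogenesis genes 14 were lower and 0 higher, 18 and 0 when adjusted over the list alone. MYC itself was 1.80-fold lower, and the nucleolar factors RRS1 (-0.63), DKC1 (-0.47) and NOP2 (-0.41) fell with it (median -0.30, or -0.28 with bounds, adjusted camera p = 7.68e-10, and adjusted p = 0.000298 with an estimated correlation). Of 21 immediate early genes 9 were lower and 0 higher, also adjusted over the list alone, among them JUN (-0.91), ATF3 (-0.86) and DUSP1 (-0.84) (median -0.21, adjusted camera p = 1.32e-06, and adjusted p = 0.0155 with an estimated correlation). In control siRNA against vector the immediate early list was called higher with the preset correlation (median 0.48), and MYC targets were called lower (-0.65).

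Several lists were higher with ZMYND8 siRNA. In control siRNA against vector the respiratory chain was called lower with the preset correlation (median -0.20). Cholesterol synthesis (-0.29), histone (-0.22), S100 (-0.12) and p53 lists (-0.0042) also had negative medians, without a call. Interferon (0.22) and G2/M lists (0.07) did not. The control siRNA arrays stand in both comparisons, which favours opposite signs. For lists of opposite sign a return toward vector cannot be told apart from a need for ZMYND8. Of 21 cholesterol synthesis genes 10 were higher and 1 lower, 12 and 1 adjusted over the list alone. Examples were IDI1 at 0.60 and ACAT2 at 0.52 (median 0.25, adjusted camera p = 2.34e-05, and adjusted p = 0.00394 with an estimated correlation). Of 19 interferon response genes 7 were higher and 0 lower, 8 and 0 adjusted over the list alone. Examples were IFIT1, 2.11-fold higher, IFI6 at 0.62 and USP18 at 0.44 (median 0.25, or 0.23 with bounds, adjusted camera p = 0.00224, and adjusted p = 0.0155 with an estimated correlation). Of 16 histone genes 4 were higher and 0 lower, 5 and 0 adjusted over the list alone. Examples were H2BC5 at 0.81 and H2AC6 at 0.77 (median 0.15, adjusted camera p = 0.00273, and adjusted p = 0.0167 with an estimated correlation). Of 31 respiratory chain genes 6 were higher and 1, SDHD (-0.92), was lower, 10 and 1 adjusted over the list alone (median 0.13, adjusted camera p = 0.000533, and adjusted p = 0.0155 with an estimated correlation). This call was lost with median scaling (adjusted p = 0.196), under which the median of all genes was -0.07. Of 22 p53 targets 8 were higher and 1 lower, 9 and 1 adjusted over the list alone. Examples were TP53INP1 at 1.14, GDF15 at 0.84, TP53I3 at 0.63 and PHLDA3 at 0.50 (median 0.17, adjusted camera p = 0.0159, but adjusted p = 0.118 with an estimated correlation). Of 10 S100 and metallothionein genes 5 were higher and 1 lower, 6 and 1 adjusted over the list alone, with MT2A at 0.41 (median 0.29, adjusted camera p = 0.014, but adjusted p = 0.073 with an estimated correlation). Of 28 G2/M genes 9 were higher and 1, BIRC5 (-1.15), was lower, also adjusted over the list alone, with CENPA at 0.54 and KIF20A at 0.48 (median 0.13, adjusted camera p = 0.0343, but adjusted p = 0.0603 with an estimated correlation). The G2/M call was lost with median scaling (adjusted p = 0.460), without ZMYND8 siRNA replicate 1 (adjusted p = 0.0514) and with the arms fitted apart (adjusted p = 0.0883). With median scaling 1828 genes were called, 569 higher and 1259 lower.

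**Figure D3:**
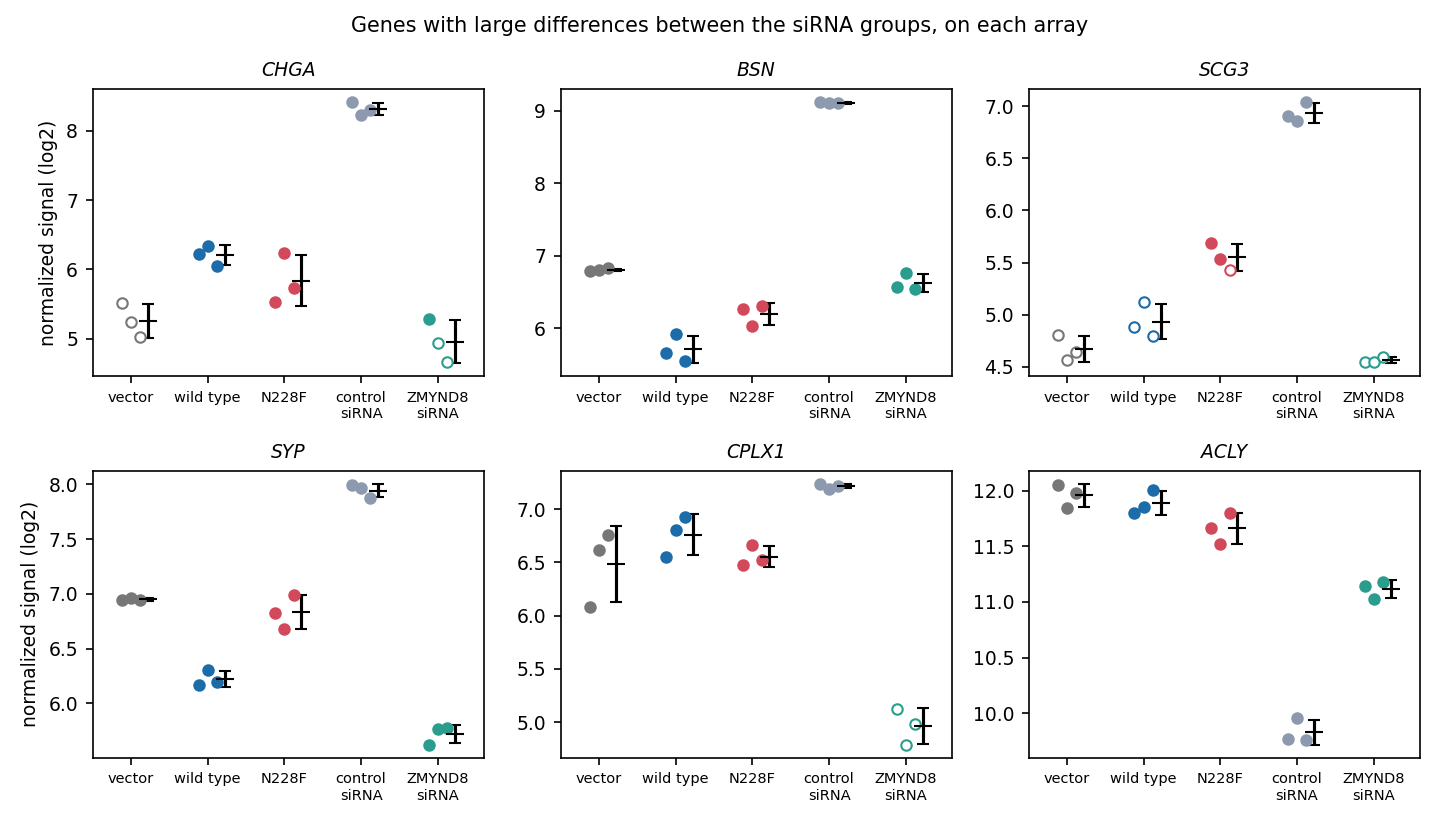
Normalized log2 signal of 6 genes on each array, by group; filled points were detected, open points were not, and the bar is the mean ± SD of 3 arrays. CHGA, BSN, SCG3, SYP and CPLX1 were highest and ACLY was lowest in control siRNA cells.

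The genes called with ZMYND8 siRNA were then followed in the overexpressing lines, which share no array with them. The 1244 genes higher with ZMYND8 siRNA were not called as a set against the other genes in wild-type cells (camera p = 0.480, and p = 0.382 with an estimated correlation) or in N228F cells (camera p = 0.119, and p = 0.0713 with an estimated correlation). Nor were the 1197 lower genes (camera p = 0.425 and 0.195, with p = 0.412 and 0.194 with an estimated correlation). Of the higher genes 354 were also higher and 462 lower in wild-type cells, where chance would give 297 and 333, and 328 were higher and 484 lower in N228F cells, where chance would give 293 and 315. Of the lower genes 378 were higher and 355 lower in wild-type cells (286 and 320 by chance), and 396 were higher and 314 lower in N228F cells (282 and 303 by chance). Without background correction the genes higher with ZMYND8 siRNA shifted downward as a set in N228F cells (camera p = 0.0354 with the preset correlation, not adjusted over the set tests). Leaving out single arrays gave p between 0.0695 and 0.572. Shared calls thus lay above the chance numbers in the same as well as in the opposite direction. The chance numbers assume independent calls. The compared groups share no array, but each gene's spread comes from the same fit over all arrays. A gene of low spread is thus more easily called in both comparisons, in any direction. The excess over chance therefore cannot be read as a shared response. The genes that follow were picked for opposite changes, so they do not show which direction prevails. CCND1 (cyclin D1) fell by 1.32 with ZMYND8 siRNA, where 2 of 3 arrays detected it, and was higher by 2.29 in wild-type and 2.35 in N228F cells. CAV1, the main protein of caveolae, fell by 1.29 and was higher by 2.43 in each line, and the globin gene HBA2 fell by 1.13 and was higher by 3.45 and 2.09. CRMP1 fell as well and was higher by 2.84 and 1.95. CUL4A (-1.13 with ZMYND8 siRNA, 1.20 in wild type) and SHISA2 (-1.05 and 1.64) went the same way, as did PRSS23 (-1.64 with ZMYND8 siRNA, 1.27 in N228F) and CHGB, at least 1.59-fold higher in N228F cells. SNORA12 was higher with ZMYND8 siRNA and lower in wild-type (-1.61) and N228F cells (-2.72), SCARNA13 was higher by 1.06 and lower in wild type (-1.63), and ZNF467, detected on 2 of 3 N228F arrays, was lower there (-1.56).

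Control siRNA cells were compared with vector cells, which is no question of the study but shows how far the arms differ. The arms differed in raw signal and in detected probes, so transfection and any difference in array run cannot be told apart. Genes of the ATF4 response were higher: DDIT3 (CHOP) was 5.26-fold higher (2.39, SE 0.08, adjusted p = 1.24e-09). CHAC1, which breaks down glutathione, was at least 2.67-fold higher, and ALDH1L2 was higher by 2.42, ATF3 by 2.37, CTH by 2.01 and ASNS by 1.70. INHBE was at least 9.32-fold higher, CHGA at least 6.77-fold, HSPB8 at least 6.52-fold, C1QTNF6 at least 4.20-fold and TCIM at least 2.73-fold, while TXNIP was 7.10-fold and BSN 4.93-fold higher and ANXA1 was higher by 2.35. TERC, the RNA of telomerase (-2.70), SCARNA13 (-2.56) and RNY1 (-2.15) were lower, as were POLR2L (-2.23) and ACLY (4.37-fold). CIRBP-AS1 was at least 4.43-fold lower, and RNA28SN5, SRSF6P2, ICAM3 and SCARNA8 were among the 12 largest falls as well, as were SCARNA23 and ATAD3B, each detected on 2 of 3 control siRNA arrays. In all 8289 genes were called, 4286 higher and 4003 lower, with 614 and 438 by at least 2-fold. With median scaling in place of quantile normalization 10758 genes were called, 10098 higher and 660 lower, and the median of all genes was 0.58, so the directions here are relative to the other genes.

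Of 27 ATF4 genes 25 were higher and 1 lower in control siRNA cells, also adjusted over the list alone (median 1.31, adjusted camera p = 2.88e-13, and adjusted p = 0.000336 with an estimated correlation). Of 27 MYC targets and ribosome biogenesis genes 24 were lower and 1 higher, also adjusted over the list alone, with NOP16 at -1.56 (median -0.65, adjusted camera p = 1.40e-09, and adjusted p = 0.000336 with an estimated correlation). Of 18 heat shock genes 17 were lower and 1 higher, also adjusted over the list alone, with HSPA8 at -1.14 and STIP1 at -1.13 (median -0.62, adjusted camera p = 1.56e-07, and adjusted p = 0.00455 with an estimated correlation). Of 31 respiratory chain genes 18 were lower and 3 higher, also adjusted over the list alone (median -0.20, adjusted camera p = 0.0101, but adjusted p = 0.0717 with an estimated correlation), a call lost with median scaling (adjusted p = 0.416) and among genes detected on all 15 arrays (adjusted p = 0.0529). With median scaling CYC1 and COX4I1, members of that list, changed sign, but both still lay below the median of all genes, 0.58 under that scaling. Of 21 immediate early genes 10 were higher and 2 lower, also adjusted over the list alone (median 0.48, or 0.40 with bounds, adjusted camera p = 0.0117, but adjusted p = 0.224 with an estimated correlation).

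**Figure D4:**
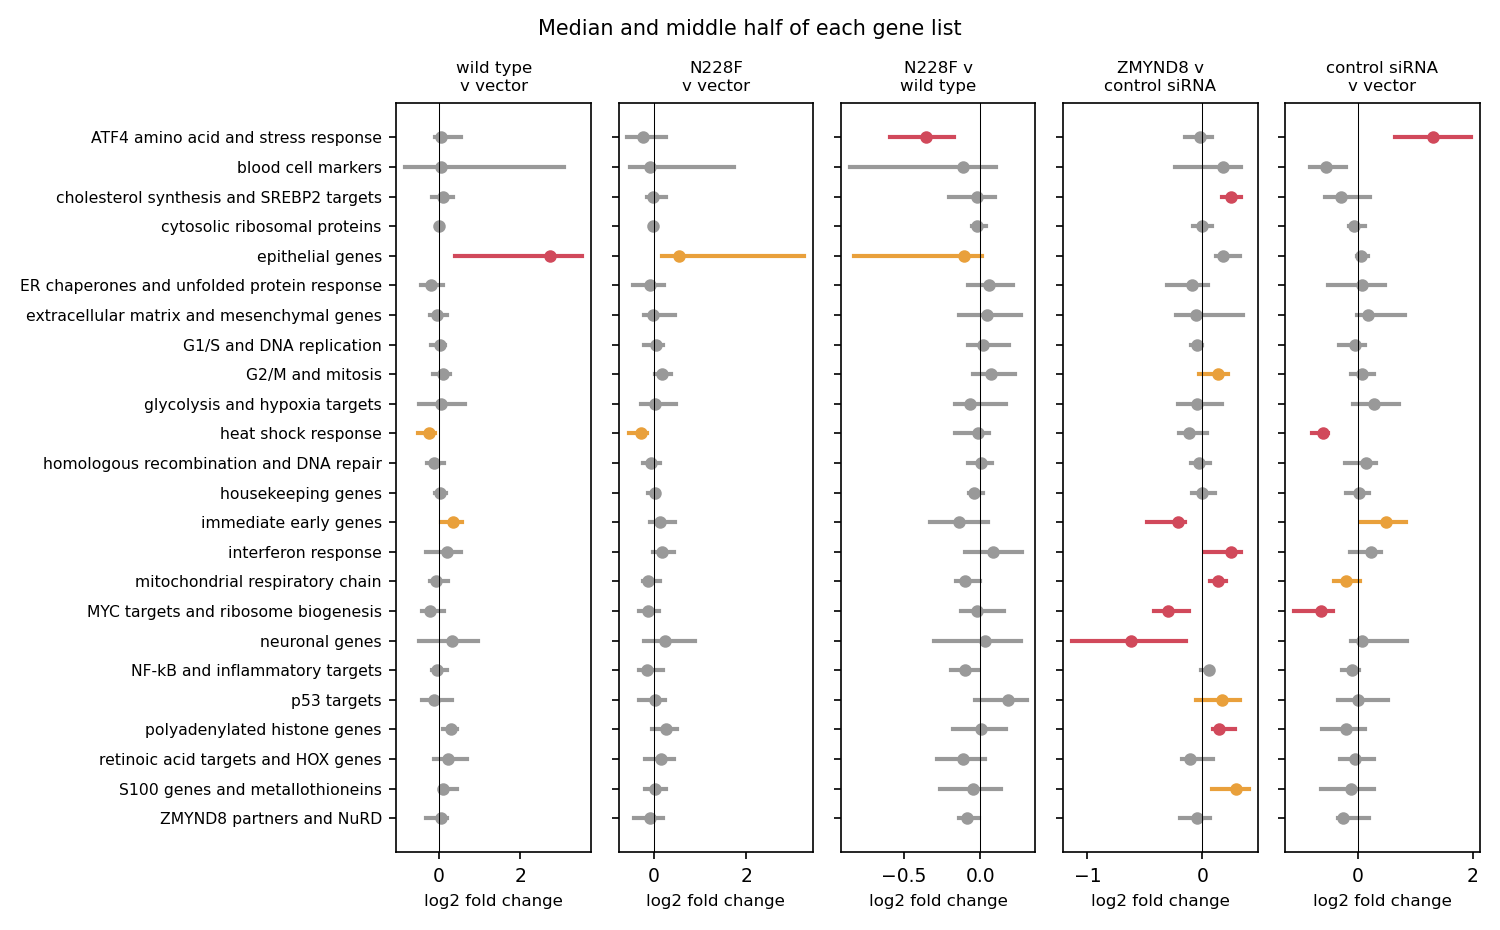
Median log2 difference (point) and 25th to 75th percentile (bar) of the measured members of each of the 24 gene lists in 5 comparisons, on axes that differ between panels. Red lists were called with the preset and the estimated correlation (12), orange lists with the preset alone, and grey lists were not called.

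Of 120 list tests 22 were called with the preset correlation and 12 with an estimated one. The remaining 11 lists were not called in any comparison. Their lowest adjusted camera p over the 5 comparisons was 0.0508 for ER chaperones, 0.0787 for blood cell markers and for extracellular matrix genes, and 0.0942 for retinoic acid targets and HOX genes. It was 0.187 for glycolysis and hypoxia targets, 0.256 for ZMYND8 partners and NuRD, 0.439 for housekeeping genes, 0.448 for G1/S genes and for NF-kB targets, 0.470 for DNA repair genes and 0.795 for cytosolic ribosomal proteins. The median, mean and test differed in sign in 14 of the 120 tests, none of them called. In wild type against vector they were G1/S genes, ZMYND8 partners, ribosomal proteins and the respiratory chain. In N228F against vector they were blood cell markers, cholesterol synthesis, extracellular matrix and housekeeping genes, and in N228F against wild type MYC targets. Between the siRNA groups they were blood cell markers and housekeeping genes, and in control siRNA against vector ribosomal proteins, housekeeping genes and p53 targets. The authors' own log2 fold changes, whose reference groups their table does not name, correlated across genes with those given here, at r = 0.859 for wild type, 0.857 for N228F and 0.907 for ZMYND8 siRNA, at slopes of 0.350, 0.347 and 0.489.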

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

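The tests named below as vector arrays that stand apart, a response in proportion to ZMYND8, subline or inducer, a rise brought by the control siRNA, a one-way response and culture state were chosen after the results were seen. Bootstrap intervals and the exact limit, here and for chromosome arms below, take genes as the unit. Genes share the same arrays and are not independent replicates, so these limits carry no spread between cultures.

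The difference from vector was not the same in the induced lines: 2805 genes differed between N228F and wild-type cells by a test of the difference itself. By the same kind of test, ATF4 genes were lower in N228F cells (median -0.35), as were epithelial genes with the preset correlation (median -0.10, 3 of 10 called lower and 7 not called). The epithelial call was lost with an estimated correlation (adjusted p = 0.145), with no detection filter (0.0542) and among genes detected on all 15 arrays (0.488). The ZMYND8 probes were higher in N228F cells by 0.92 (base 4164), 0.78 (base 3413) and 0.71 (base 4068).

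Both induced lines differed from vector in many of the same genes. Vector arrays that stand apart from other cells without a construct are argued against for the largest differences only. Of 170 genes at least 4-fold different the same way in both lines, 165 (97.1%, lower exact 95% limit 93.3) lay nearer to vector in control siRNA cells. Smaller differences were not covered by this test, and 8289 genes were called in control siRNA against vector. A response in proportion to the ZMYND8 transcript stays open. Of the 483 genes higher by at least 2-fold in both lines, 301 were detected on all control siRNA arrays and could fall. Their median change with ZMYND8 siRNA was 0.0399 (bootstrap 95% interval 0.00243 to 0.0729), but they went both ways, with 43 called higher, 38 lower and quartiles of -0.168 and 0.233. The 266 genes lower by at least 2-fold in both lines had a median change of 0.0741 (0.0209 to 0.109), across the rise of 0.1 set as the bound, with 39 called higher and 24 lower. A different subline of origin or the inducer may also account for it, since 111 genes were detected on all 6 arrays of the induced lines and on none of the 9 others, and 90 the other way round. These cannot be told apart from ZMYND8 itself, because each induced line carries a construct, went through selection and was given the inducer, and the labels do not say whether vector cells received it.

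Neuronal genes were lower with ZMYND8 siRNA than with control siRNA. A rise brought by the control siRNA stays open as a part of it. Over the 24 measured genes the median was 0.0659 in control siRNA against vector (bootstrap 95% interval -0.0697 to 0.745). It was -0.301 in ZMYND8 siRNA against vector (-0.684 to -0.0518). These medians fall on different genes and do not add up to the median of -0.624 between the siRNA groups. The list's mean was 0.350 in control siRNA against vector and -0.776 in ZMYND8 siRNA against control siRNA. The share of the difference that lies below vector thus depends on the statistic. Of the bootstrap intervals, the first reaches a rise of 0.745 and the second comes close to vector, so neither decides. A change in REST, the repressor of neuronal genes, was to be tested before its level was seen, but its probe was detected on 0 of 15 arrays. All 12 of the genes with the largest falls were called higher in control siRNA than in vector cells, which was seen through the same control siRNA arrays that selected them. A need for ZMYND8 stays open as well, since both comparisons with vector also carry the differences in raw signal and detection between the arms.

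ATF4 genes were lower in N228F than in wild-type cells. A single array as the cause is argued against, since the adjusted camera p stayed between 5.75e-09 and 1.87e-07 without any 1 of the 6 arrays. A one-way response to more ZMYND8 transcript stays open: the list's median was 0.0458 in wild type against vector (bootstrap 95% interval -0.0561 to 0.395) and -0.226 in N228F against vector (-0.448 to 0.0907). Culture state at harvest could also move the list, which differed by 1.31 (0.894 to 1.70) between control siRNA and vector cells, groups without a construct. The mutation, the level of ZMYND8 and the culture cannot be told apart with 1 line of each kind.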

How the results depend on the processing

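The fit of each arm, and the authors' values, median scaling, other detection filters, variance models and array weights for the list tests, the knockdown genes in overexpression or the correlation of the lines, were chosen after seeing the data. Apart from leaving out arrays, 56 counts of genes stayed within 1.5 times the reported number and 12 did not. Without any 1 array 29 did and 1 did not. At a 1.5-fold minimum 3284 genes were called in wild type, 3099 in N228F, 803 between the lines, 620 with ZMYND8 siRNA and 3887 in control siRNA, and at an adjusted p of 0.01 1470 between the lines and 1294 with ZMYND8 siRNA, fewer by construction. ZMYND8 siRNA gave 3994 calls with the authors' values, 3821 with array weights and 1624 to 1803 without any 1 array. N228F against wild type gave 1617 with median scaling, 1806 with the arms apart and 1215 with only these groups. Gene list calls numbered 12 with the estimated correlation and 83 with fry, which compares no list with other genes. In control siRNA against vector, median scaling turned ZMYND8 probes 4164 (0.57) and 4068 (0.54), CYC1 (0.0032) and COX4I1 (0.0301), where the median of all genes was 0.58. The knockdown genes in overexpression gave no set call except p = 0.0354 (higher genes in N228F, no background correction), and their uncalled direction turned for lower genes in wild type with no background correction (p = 0.970) and the authors' values (0.928), and for higher genes with median scaling (0.110 in wild type, 0.616 in N228F). Without any 1 array the p of higher genes in wild type ran from 0.316 to 0.963 and turned without siControl replicates 2 and 3 and siZMYND8 replicate 3. The correlation of the lines was 0.855 without a detection filter and 0.857 among genes detected on all 15 arrays, where the slope was 0.827. Uncalled ZMYND8 probe 4068 in wild type ran from -0.12 to 0.000929, and probe 3413, not detected in either siRNA group, from -0.17 to 0.00698. Other causes were not tested. Apart from leaving out arrays, named genes were unchanged in call and direction 2203 times, lost a call 22 times, gained 1 in 3 and turned in 2. Without any 1 array they were unchanged 1306 times, lost a call 6 times and gained 1 in 2. Replicate numbers did not pair the arrays (r of residuals -0.0563 to 0.128 over 30 pairs), and a replicate block gave 7543, 7293, 2773, 2395 and 8297 calls in the 5 comparisons. The authors' numbered table columns could not be mapped and the files name no slide, so these alternatives were not run. Signal over background limits genes near the floor. Calls that rest on a group with no detection numbered 891 in wild type, 817 in N228F and 203 between the lines. They numbered 63 with ZMYND8 siRNA and 721 in control siRNA against vector.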

Other observations

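The arm tests below were written before their results were seen, except that the test of the median difference of all called genes was chosen after the results were seen, as was the view that the count of genes at least 2-fold different decides nothing. The count of genes by their place relative to vector was chosen after the siRNA results were seen as well.

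MYC was lower (-0.85) with ZMYND8 siRNA, higher by 0.57 in wild-type cells and differed by 0.05 without a call in N228F cells, with a called difference between the lines of -0.53 (adjusted p = 0.000658). GSTM1 was higher by 0.57 with ZMYND8 siRNA. Among the 118 genes called with at least a 2-fold change between the siRNA groups, 57 lay nearer to vector with ZMYND8 siRNA than with control siRNA, 39 of the 85 lower and 18 of the 33 higher genes.

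Genes of 1 chromosome arm shifted together between the lines. Over 41 arms with at least 50 tested genes each (13345 genes), the SD of the arm medians was 0.209 in wild type against vector, where the highest of 1000 permutations of genes over arms gave 0.0511, and 0.190 in N228F against vector (0.0499). It was 0.129 between N228F and wild type (0.0283) and 0.0226 between the siRNA groups, inside the permutations (0.026). By a rank-sum test of each arm against the others, 19q (0.076, adjusted p = 2.16e-07) and 20p (-0.046, adjusted p = 0.0274) still had small called shifts between the siRNA groups. Control siRNA against vector gave 0.0909 (0.0553). The arms 8p (0.64 and 0.56), 5p (0.48 and 0.45) and 3p (-0.35 and -0.39) shifted in both lines, and between the lines 20p (0.49), 16p (0.39), 19p (0.30), 20q (0.29) and 21q (-0.21) did. In control siRNA against vector, groups without a construct, 19p (-0.20) and 16p (-0.16) were among the largest shifts too, so these arms need not differ by the copy number of the lines, while 8p (0.02), 5p (-0.01) and 3p (0.02) had no called shift. On 20q, the arm of ZMYND8, 80.4% of 225 genes were higher in N228F than in wild-type cells. The arms beyond 0.2 held 9.16% of the genes on arms and 24.1% of the calls between the lines (638 of 2644). A candidate explanation is that the copy number of whole arms differs between the stable lines and the parental cells, which the arrays could not measure. Over all called genes, shifts shared by a whole arm made up a small part of the difference from vector. Subtracting each arm's median lowered the median absolute log2 difference of the 7063 called genes on arms in wild type against vector by 12.5% (bootstrap 95% interval 11.2 to 14.1), where a main part was to exceed 50%. That bound was set with the arm medians known, and their size limits this fall as well, so missing it decides nothing further. Copies of parts of an arm were not tested. The fall was 11.6% in N228F against vector and 16.2% between the lines. For genes at least 2-fold different, whole arms as the main part of the difference stay open. These genes fell from 1058 to 959 in wild-type cells, by 9.36% (5.94 to 12.7), across the 10% written beforehand as the bound. Arm medians of 0.64 at most limit how far this count could fall.

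Other splits of the 6 arrays of each comparison, with those groups fitted alone, gave 0 called genes at most by limma, and 1 of 10 splits, the real one, gave as many as observed: 6238 genes in wild type against vector, 5932 in N228F against vector, 1215 between the lines, 3185 with ZMYND8 siRNA and 8183 in control siRNA against vector. At an unadjusted p under 0.05 the highest other split gave 345, 332, 747, 504 and 193 genes, in the same order. In each comparison 10 splits are too few for a share under 0.05.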
